A study of Mus musculus with 4 samples.

How the data were processed

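The series holds 4 arrays, each hybridised with 1 biotin-labelled RNA sample recovered by immunoprecipitation from lysed early erythroid progenitors of embryonic day 14.5 mouse fetal liver. Groups were taken from the sample titles, with 2 arrays from control rabbit IgG and 2 from an antibody against an RNA-binding protein. RNA was amplified and labelled with a whole-transcript expression kit, per the labels. The values deposited are log2 levels per probe set, made by the authors with RMA and the affy tool, per the submitters' processing notes. Their versions, the background step and any filter are not given in the sources used here. The log2 scale was taken from the values, which run from 1.83 to 13.87, and from the mention of RMA. The 4 columns differ in median and spread, so no step after summarisation had made their distributions equal. No scanner files were used here.

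Of 35556 probe sets, 21789 had 1 gene symbol in the platform annotation, 1621 had several and 12146 had none there. For 21698 of the 21789 the Entrez identifier was found in the RefSeq gene table of assembly GRCm38.p6, used for names alone, which changed 0 symbols. Each of the 19938 genes was represented by the probe set with the highest mean over all arrays. Of the 999 genes with more than 1 probe set, 16 had probe sets called in opposite directions. No filter on level was set for the tests. All columns of values were used.

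Differences were tested in R 4.3.3 with limma 3.58.1 on the deposited log2 values (lmFit and eBayes without trend or robust options), as RBP minus IgG, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The residual degrees of freedom were 2 and the prior degrees of freedom 3.76. A size rule counted genes at least 2-fold apart with no overlap between groups. Gene lists were tested with camera at a preset correlation between genes of 0.01 and again with an estimated one, and with fry, which tests whether a list's genes move on balance one way. Each list's median was also ranked among 10000 random lists drawn from 20 bins of mean level. Percentiles describe these arrays and are not tests between conditions. Replicate arrays were compared by Pearson's r across genes.

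The main test, the alternatives, the 21 gene lists and the rule for named genes were set before the data were examined. The rule took the 12 genes with the largest positive and the 12 with the largest negative difference among called genes without overlap, leaving out small RNAs, chemosensory receptors and predicted models. From each list it took up to 4 called members with the largest absolute difference, or 2 members where none was called. A fixed set of erythroid, Zfp36-family and reference genes was always named, except Gapdh, for which no probe set carried the symbol alone. The lists cover terminal erythroid genes, heme synthesis and iron, erythroid transcription regulators, stem and progenitor genes, AU-rich mRNAs, immediate early genes, the glucocorticoid response, erythropoietin and KIT signalling, the cell cycle, CCR4-NOT and decay, and markers of hepatocytes, macrophages, megakaryocytes, granulocytes and mast cells, lymphoid cells, and endothelial and stromal cells. Ribosomal proteins, replication histones, small RNAs, chemosensory receptors and predicted models were taken by symbol pattern. Several lists share genes, above all the AU-rich list with the immediate early, cell cycle and decay lists. The terminal erythroid and heme lists share Tfrc, the transferrin receptor, whose difference is the median of both.

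The alternatives were quantile normalization, centring on the median of the chemosensory genes, filters at the median gene and at the 95th percentile of the chemosensory genes (5.34), the mean over a gene's probe sets, the replicate number as a block, leaving out each array, eBayes with trend and robust options, no variance moderation, all probe sets, a test against a 1.2-fold change and a threshold of 0.1. Removal of the loess trend (span 0.3) of the difference on mean level, and array weights, were added after the data had been seen.

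The test was tried on simulated data with the level and spread of these genes. With 50 changed genes at each of 4 sizes it called 42 of 50 at a log2 change of 2 and 0 of 50 at 0.5, at 1 and at -1, with 1 false call. With a larger share of genes changed, all upward, it called 25.9% at 0.5, 72.7% at 0.8, 93.7% at 1.2 and 98.9% at 2, and 2.83% of calls were false. A simulated trend on level alone gave 6159 calls, and 0 after its removal. Of 21 simulated lists, the 1 that was shifted was called and 0 others. The simulated genes varied independently, whereas the estimated correlation on the real arrays was 0.326 for the ribosomal protein list. The simulated variances were drawn from the distribution that limma had fitted to these arrays, which favours the test. Apart from the trend on level, no difference in spread over whole arrays was built in. These rates may therefore not carry over to the reported comparison. Arrays give no read depth, and the precision here is limited by 2 arrays per group. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.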

Results

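RNA recovered by immunoprecipitation from mouse early erythroid progenitors was measured on Affymetrix whole-transcript gene arrays. The cells came from C57BL/6 fetal livers at E14.5. They had been depleted of cells bearing lineage markers, Sca-1, CD16/32, CD41 or CD34 and then sorted for c-Kit with low CD71, which keeps progenitors that precede the haemoglobin-making erythroblasts. Of the 4 arrays, 2 held RNA pulled down with control rabbit IgG and 2 held RNA pulled down with an antibody against an RNA-binding protein (RBP). The labels do not name the protein. It is taken here to be ZFP36L2 from what is known of the published study, an identity not checked against the antibody. ZFP36L2 is a zinc finger protein of the tristetraprolin family, which binds AU-rich elements in the untranslated ends of mRNAs.

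Each array gave a log2 level for 35556 probe sets, and 21789 of these carried a single gene symbol and stood for 19938 genes. The median level was 5.85 and 5.93 on the IgG arrays and 5.57 and 5.62 on the RBP arrays. The interquartile range was wider on the RBP arrays (3.73 and 3.61) than on the IgG arrays (2.91 and 2.87). Across genes, which are not independent replicates, Pearson's r was 0.977 between the IgG arrays, 0.993 between the RBP arrays and 0.952 to 0.959 between arrays of different groups. Nothing in the labels says whether the arrays of a group came from separate cell preparations, so the p-values below measure the spread between these arrays, which may be technical. The number of arrays limited the precision, and the median standard error of a log2 difference was 0.170.

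The comparison of the RBP with the IgG immunoprecipitates asked which transcripts the RBP antibody recovered beyond control IgG. A large set of mRNAs was higher on the RBP arrays. Among them were Cenpf, a kinetochore protein of dividing cells (4.62-fold), Bod1l, which protects replication forks (4.87-fold), and Rps6ka3, a kinase downstream of ERK (4.66-fold). Enriched and depleted here mean higher and lower on the RBP arrays than on the IgG arrays. A compressed IgG signal and broad mRNA recovery by the RBP antibody cannot be told apart in this design. Small noncoding RNAs were among the largest depletions, with the box C/D RNA Snord118 at 9.92-fold lower and Snord82 at 11.8-fold lower. Of 30 replication-dependent histone genes 18 were lower, and 17 of 62 ribosomal protein genes were lower. In limma's moderated test with Benjamini-Hochberg adjustment over 19938 genes, 4741 genes (23.8%) were higher and 1304 (6.54%) were lower in the RBP immunoprecipitates at an adjusted p under 0.05.

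By size alone, 2690 genes were at least 2-fold higher and 246 at least 2-fold lower with both arrays of one group above both of the other. Groups separated in this way, at any size, for 73.7% of genes, against 33.3% if the arrays of a gene were in random order. Genes are not independent, and the groups differed in median and spread over whole arrays, so this share is no test. The split of calls depended on how the arrays were scaled. Centring each array on the chemosensory receptor genes, which these cells are not known to use, moved the median of all genes from -0.02 to 0.29 and gave 7081 higher and 317 lower, while quantile normalization moved that median to 0.16 and gave 2207 higher and 553 lower. No gene called in both of these settings and in the reported fit changed direction. Without RBP array 1 the counts were 1724 higher and 99 lower, without RBP array 2 they were 2058 and 151, and without IgG array 2 they were 4917 and 2905. Of the 105 genes named here, 30 lost their call without RBP array 1 and 28 without RBP array 2, and no called one changed direction in any setting. Without an RBP array the variance was measured on the IgG pair alone. The SD of the difference between arrays was 0.401 for that pair and 0.258 for the RBP pair. A call lost without an RBP array need not mean a smaller difference. The 2-fold rule, which uses no variance, gave 2659 higher and 266 lower without RBP array 1. It gave 2871 and 268 without RBP array 2, though fewer arrays make no overlap easier to meet. An exact two-sided permutation p of 2 arrays against 2 cannot fall below 0.333. Nearly all calls therefore rest on limma's sharing of variance across genes, and without it 2 genes were called higher and 1 lower.

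The largest enrichments outside the small RNA, receptor and predicted-gene families spanned 2.20 to 2.52 on the log2 scale. Pdxp, which encodes pyridoxal phosphatase, led with a level of 8.98 ± 0.45 (SD, n = 2) against 6.46 ± 0.11, a difference of 2.52 ± 0.24 (SE; limma, adjusted p = 0.00558). Tjp1, the tight junction scaffold ZO-1, differed by 2.47 ± 0.18, and Ipp, a kelch-repeat actin-binding protein, by 2.41 ± 0.16. Med31, a subunit of the Mediator complex, differed by 2.31 ± 0.25, and Klhl12, an adaptor of a cullin-3 ubiquitin ligase, by 2.30 ± 0.15. The zinc finger gene Zfp322a differed by 2.30 ± 0.15 and the mismatch repair gene Mlh3 by 2.29 ± 0.20. Bod1l (2.28 ± 0.15), Rps6ka3 (2.22 ± 0.20), Cenpf (2.21 ± 0.15), Golgb1, the Golgi matrix protein giantin (2.20 ± 0.17), and Insig2, an endoplasmic reticulum sterol sensor (2.20 ± 0.17), completed the group. All 12 shared limma's adjusted p of 0.00558. The IgG levels of Tjp1 (4.99) and Ipp (4.96) lay below 5.34, the 95th percentile of the chemosensory receptor genes and taken here as the background level, so the sizes and ranks of these differences are uncertain.

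The largest depletions were mostly of noncoding RNAs and their host genes. AY036118, a transcript of no known protein, was lowest, at 8.45 ± 0.61 (SD, n = 2) against 12.45 ± 0.26, a difference of -3.99 ± 0.31 (SE; limma, adjusted p = 0.00558). The vault RNA Vaultrc5 differed by -2.73 ± 0.36, the Y RNAs Rny1 and Rny3 by -2.47 ± 0.72 and -2.01 ± 0.43, the RNase P-like RNA Rprl2 by -2.15 ± 0.14 and the telomerase RNA Terc by -1.97 ± 0.17. Rny1 passed narrowly (limma, adjusted p = 0.0487), as its IgG arrays differed by more than 2 log2 units, and its call was lost under either scaling above and without either RBP array (adjusted p up to 0.114). Rny3 lost its call without IgG array 1 (adjusted p = 0.0507) or RBP array 2 (adjusted p = 0.0619). The RBP levels of Vaultrc5 (4.39) and Rny1 (3.40) lay below the background level of 5.34, so the sizes and ranks of their differences are uncertain. Snhg17 (-2.58 ± 0.45) and Taf1d (-2.06 ± 0.33) carry small nucleolar RNAs in their introns, and their probe sets cannot be separated from those RNAs here. The histone genes H2bc3 (-2.15 ± 0.19) and H2bc9 (-1.86 ± 0.17) and the mitochondrially encoded ND3 (-1.83 ± 0.30) were also lower. Fcer1g, the common gamma chain of Fc receptors, was the remaining mRNA in this group, at -2.78 ± 0.50 (limma, adjusted p = 0.0123).

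**Figure D1:**
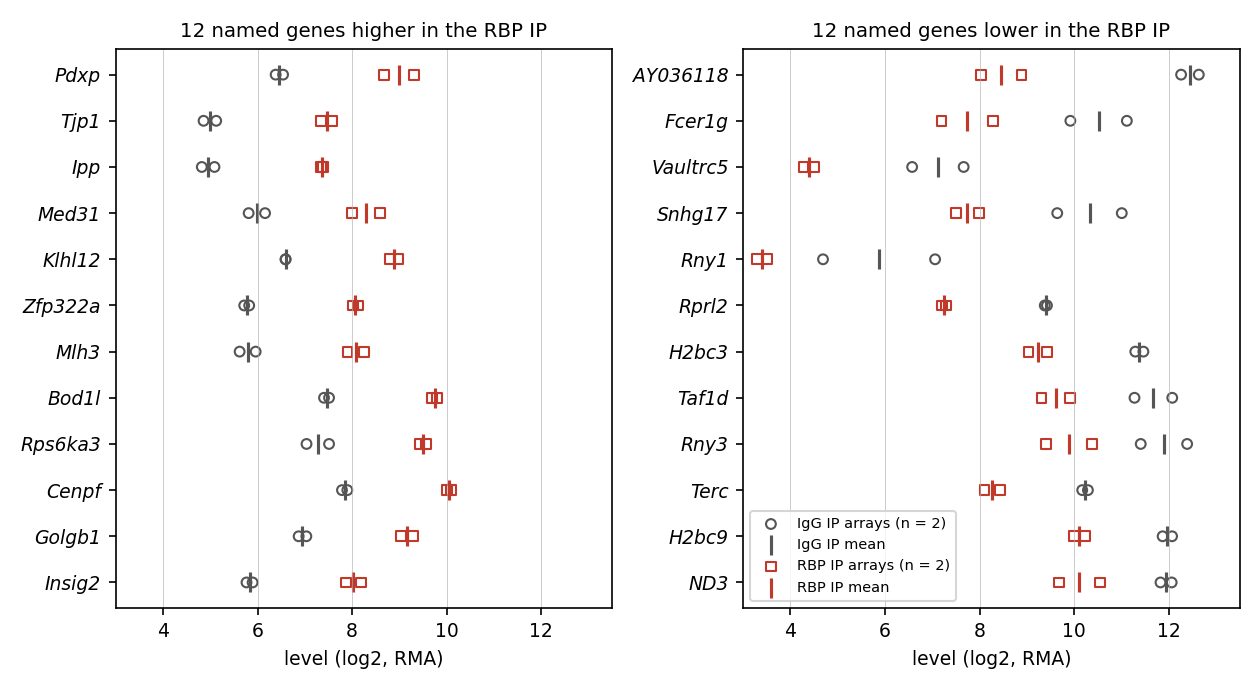
Level (log2, RMA) of the 12 genes with the largest enrichment (left) and the 12 with the largest depletion (right) in the RBP immunoprecipitates, with each array as an open symbol (n = 2 per group) and group means as vertical bars. Both RBP arrays lay above both IgG arrays for every gene on the left, Pdxp leading with 2.52, and below them for every gene on the right, AY036118 leading with -3.99.

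The direction of the difference went with the level of the gene. Genes with a mean level above the background level of 5.34 numbered 12908, and 4687 of them (36.3%) were higher and 848 lower. Among the 7030 genes at or below that level, 54 were higher and 456 lower. The median difference was -0.23 for genes at mean levels of 4 to 5, 0.16 at 6 to 7, 0.66 at 7 to 8, 0.78 at 8 to 9 and 0.56 above 10. After this trend on level was subtracted, a setting chosen after the trend had been seen, limma called 999 genes higher and 1065 lower, of which 978 and 522 were also called before.

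**Figure D2:**
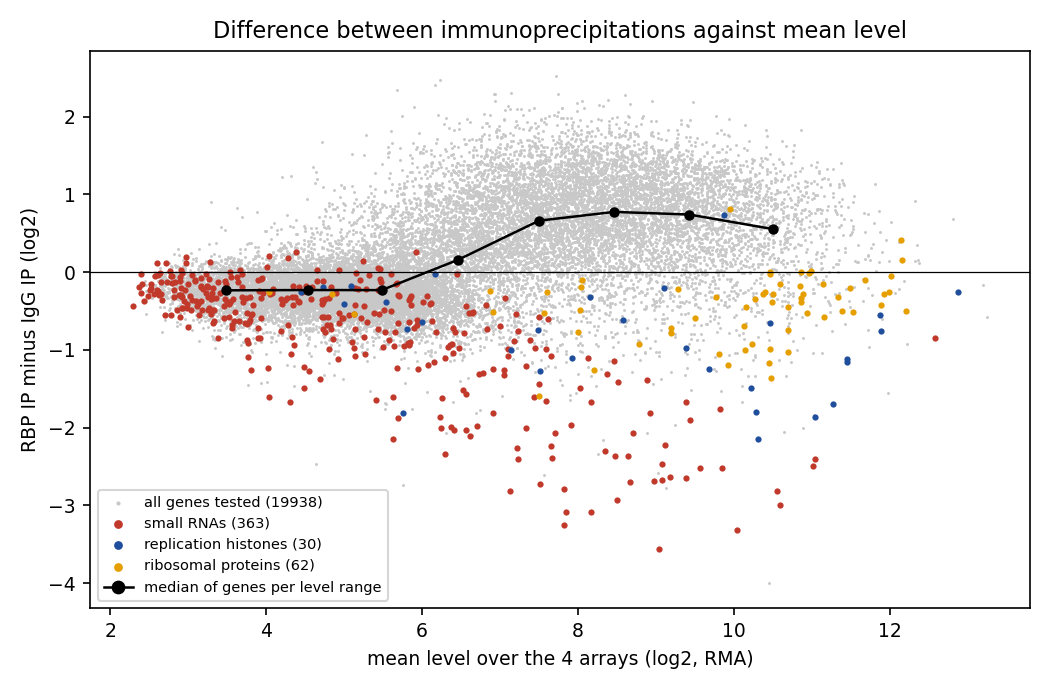
Difference between the RBP and IgG immunoprecipitates (log2, mean of 2 arrays minus mean of 2 arrays) against the mean level over the 4 arrays (log2, RMA) for 19938 genes, with small RNAs in red, replication histones in blue, ribosomal proteins in orange and the median per level range as a black line. The line runs from -0.23 at low levels to 0.78 at levels of 8 to 9, and many small RNAs, histones and ribosomal proteins lie below it.

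The mRNA of Zfp36l2 itself was abundant and higher in the RBP immunoprecipitates, at 12.05 ± 0.25 (SD, n = 2) against 11.29 ± 0.04, a difference of 0.76 ± 0.18 (SE; limma, adjusted p = 0.0255). Genes with a mean level above 10 had a median of 0.56, and with the level trend removed the difference was 0.31 (limma, adjusted p = 0.314). Its paralog Zfp36l1 was lower by limma, with a difference of -0.91 ± 0.27 (adjusted p = 0.0493), a call lost after centring on the chemosensory genes. Zfp36, which encodes tristetraprolin, gave -0.38 ± 0.24 and did not pass (limma, adjusted p = 0.263), but was called lower with the level trend removed (-1.08, adjusted p = 0.0478), and it differed by -0.68 without RBP array 1 and -0.08 without RBP array 2. Kit, the stem cell factor receptor used in the sort, was higher by 0.69 ± 0.19 (limma, adjusted p = 0.0439). Epor, the erythropoietin receptor, was higher by 0.87 ± 0.19 (limma, adjusted p = 0.0210). Both calls were lost with quantile normalization, where Kit differed by 0.69 (limma, adjusted p = 0.0709) and Epor by 0.46 (adjusted p = 0.186). With the level trend removed, Kit differed by 0.20 (limma, adjusted p = 0.551) and Epor by 0.16 (adjusted p = 0.627). Without RBP array 1 none of Zfp36l2, Zfp36l1, Kit and Epor passed (limma, adjusted p from 0.126 to 0.218), and none passed without RBP array 2 (0.0654 to 0.255), nor did Zfp36l1 and Kit without IgG array 1 (0.0573 and 0.0800). Gata1 (0.22 ± 0.19), Klf1 (0.52 ± 0.25) and Myb (0.28 ± 0.18), transcription factors of the erythroid and progenitor programmes, did not pass, with adjusted p of 0.400, 0.165 and 0.271 in limma. The difference of Gata1 turned negative with quantile normalization, and all 3 turned negative with the level trend removed. Klf1 passed after centring on the chemosensory genes (0.84, adjusted p = 0.0445), and without RBP array 1 or RBP array 2 it differed by 0.88 or 0.17, Gata1 by 0.44 or 0.01 and Myb by 0.42 or 0.15. The embryonic globin Hbb-bh1 (-0.37 ± 0.17, limma adjusted p = 0.151) and the actin gene Actb (-0.16 ± 0.16, limma adjusted p = 0.461) did not pass either, and both turned positive with quantile normalization, Hbb-bh1 at levels below background and Actb also after centring on the chemosensory genes. Hbb-bh1 passed as lower without IgG array 2 (-0.53, adjusted p = 0.0400).

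Many erythroid genes were enriched, with list medians that did not stand out from those of random lists of like level. Of 29 terminal erythroid genes measured, 10 were higher and 19 did not pass, with 14 higher when adjusted over the list alone. Sptb, the erythroid beta-spectrin, differed by 1.67 ± 0.16 (SE; limma, adjusted p = 0.00558), the membrane skeleton protein Epb42 by 1.38 ± 0.18, the erythroblast membrane gene Cldn13 by 1.29 ± 0.32 and the water channel Aqp1 by 1.15 ± 0.16. Of 23 genes of heme synthesis and iron handling, 10 were higher and 13 did not pass, with 12 higher when adjusted over the list alone. They included the mitochondrial transporter Abcb10 (1.79 ± 0.14), the iron regulatory proteins Ireb2 (1.75 ± 0.15) and Aco1 (1.2 ± 0.16) and the heme exporter Flvcr1 (1.22 ± 0.20), for which 1 of 2 probe sets was called and the other gave 0.03. Of 34 erythroid transcription regulators, 14 were higher and 20 did not pass, with 17 higher when adjusted over the list alone. Nfe2l1 (1.37 ± 0.17), the demethylase Kdm1a (1.31 ± 0.16), Mafk (1.23 ± 0.16) and Bach1 (1.21 ± 0.18) led that list. Without 1 of the RBP arrays, Cldn13 (adjusted p up to 0.111), Aqp1 (0.0510), Flvcr1 (0.0590) and Bach1 (0.0576) lost their calls. The numbers of higher genes in the 3 lists were 3, 4 and 4 without RBP array 1, 3, 4 and 6 without RBP array 2, 2, 4 and 4 with quantile normalization, and 20, 14 and 22 after centring on the chemosensory genes. The list medians were 0.60, 0.60 and 0.50, and limma's camera test placed all 3 lists higher than other genes (adjusted p = 0.00378, 0.00764 and 0.000574), but adjusted p was 0.303, 0.254 and 0.178 with an estimated correlation. Over 15 alternatives the adjusted p ran up to 0.866, 0.878 and 0.853. Among 10000 random lists of like level these medians stood at percentiles 65.1, 45.6 and 13.8. With the level trend removed, 2, 3 and 0 genes of the 3 lists were higher and 1 of each was lower. Of the genes named from these lists, only Sptb, Epb42, Abcb10 and Ireb2 then kept their calls.

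Cell cycle and cytokine signalling genes had the highest list medians. Of 37 cell cycle genes, 23 were higher and 14 did not pass, with 25 higher and 1 lower when adjusted over the list alone. Rbl2, a pocket protein of the retinoblastoma family, differed by 1.63 ± 0.15 (SE; limma, adjusted p = 0.00558), E2f3 by 1.30 ± 0.16, the replicative helicase subunit Mcm2 by 1.30 ± 0.16 and Rbl1 by 1.21 ± 0.16. Of 31 genes of erythropoietin and KIT signalling, 15 were higher and 1 was lower (21 and 2 when adjusted over the list alone). Jak2, the kinase bound to the erythropoietin receptor, differed by 1.47 ± 0.15, Pik3ca by 1.39 ± 0.14, Irs2 by 1.24 ± 0.16 and Fyn by 1.23 ± 0.15. The numbers of higher genes in the 2 lists were 5 and 5 without RBP array 1, 8 and 7 without RBP array 2, 10 and 7 with quantile normalization, and 29 and 25 after centring on the chemosensory genes. With the level trend removed, 3 and 1 genes of the 2 lists were higher and 1 of each was lower. The medians of 0.75 and 0.69 with no trend removed lay at percentiles 87.7 and 77.5 of random lists of like level. Camera called both higher (adjusted p = 1.28e-06 and 8.66e-05), with an adjusted p of 0.178 for each with an estimated correlation. Of the 6 lists that camera called higher, the cell cycle list alone also passed with quantile normalization and among genes above the chemosensory level, and none passed with the level trend removed.

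Some mRNAs of the deadenylation and decapping machinery were enriched, with a list median below that of random lists of like level (0.38 against 0.67). Of 35 such genes, all above the background level, 15 were higher and 1 was lower, the same counts as when adjusted over the list alone. Among all genes above that level 36.3% were higher. Cnot8, a deadenylase subunit of CCR4-NOT, differed by 1.89 ± 0.18 (SE; limma, adjusted p = 0.00558), the decapping enzyme Dcp2 by 1.88 ± 0.18, and its partners Edc3 by 1.51 ± 0.27 and Dcp1a by 1.37 ± 0.16. Edc3 lost its call without RBP array 2 (adjusted p = 0.0549), when 6 genes of the list were higher, against 7 without RBP array 1 and 8 with quantile normalization. The median was 0.38, or 0.23 without RBP array 2, and with all arrays it lay at percentile 1.70 of random lists of like level. With the level trend removed, 3 genes of the list were higher, among them Cnot8 and Dcp2, and 7 were lower. Camera did not call the list lower in that setting (adjusted p = 0.50). Camera called the list higher (adjusted p = 0.0198), but adjusted p = 0.255 with an estimated correlation, and the direction relative to other genes turned with quantile normalization.

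mRNAs known for AU-rich elements did not stand out from others. Of 48 measured, 15 were higher and 1 was lower (16 and 3 when adjusted over the list alone, 2 and 4 with the level trend removed). The chemokine Cxcl2 differed by 2.01 ± 0.33 (SE; limma, adjusted p = 0.00994), Tnf by 1.54 ± 0.32, the survival gene Bcl2 by 1.41 ± 0.19 and Hif1a by 1.36 ± 0.17. The IgG level of Cxcl2 (4.74) lay below the background level of 5.34, so the size of its difference is uncertain. The list median was 0.25 against 0.40 for random lists of like level, percentile 15.8. It was 0.51 without IgG array 1 and 0.51 without RBP array 2, above random lists of like level (0.44 and 0.41), and 0.12 without RBP array 1. Camera did not call the list (adjusted p = 0.119, and adjusted p = 0.610 with an estimated correlation), and its direction turned with quantile normalization. Without RBP array 2 it was called higher (adjusted p = 0.0157, of a range from 0.0157 to 0.913 over 15 alternatives), while Tnf then lost its call (limma, adjusted p = 0.0702). The number of higher genes was 5 without RBP array 1, 6 without RBP array 2 and 7 with quantile normalization.

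Of 27 immediate early genes measured, 4 were higher and 23 did not pass, with 3 higher when adjusted over the list alone. The 4 were the phosphatases Dusp1 (0.80 ± 0.15, limma adjusted p = 0.0150) and Dusp2 (0.72 ± 0.21), the AP-1 subunit Jun (0.69 ± 0.14) and Ier5 (0.63 ± 0.14). All 4 lost their calls without either RBP array (limma, adjusted p from 0.0928 to 0.294), Dusp2 also without IgG array 2 (0.0949). The median was 0.01 against 0.56 for random lists of like level, percentile 0.080. It was 0.18 without IgG array 1, -0.19 without IgG array 2, -0.27 without RBP array 1 and 0.23 without RBP array 2. The camera test placed the list lower although its median and mean were above 0. Camera did not call the list (adjusted p = 0.769, and adjusted p = 0.936 with an estimated correlation). At the preset correlation it called the list lower with quantile normalization (adjusted p = 0.0160) and among genes above the median gene (adjusted p = 0.00661). It also did so with the level trend removed (adjusted p = 0.00392), but not when the correlation was then estimated (camera, adjusted p = 0.901). The estimated correlation of this list was 0.475 in the reported fit. The direction turned without IgG array 1 (adjusted p = 0.996) or RBP array 2 (adjusted p = 0.323).

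Of 27 stem and progenitor genes, 8 were higher and 2 lower, as when adjusted over the list alone. Nr3c1, the glucocorticoid receptor, differed by 1.60 ± 0.22 (SE; limma, adjusted p = 0.00680), Igf2bp1, an mRNA-binding protein, by 1.02 ± 0.17, Lmo4 by 0.82 ± 0.17 and Gata2 by 0.79 ± 0.21. Without RBP array 1, Igf2bp1, Lmo4 and Gata2 lost their calls (limma, adjusted p = 0.0542, 0.146 and 0.272), Igf2bp1 and Lmo4 also without RBP array 2 (0.0771 and 0.0853), and Gata2 without IgG array 1 or 2 (0.0747 and 0.0758). The counts of the list were 1 higher without RBP array 1, 2 higher without RBP array 2, 7 higher and 4 lower without IgG array 2, and 1 higher and 3 lower with quantile normalization. Camera did not call the list (median 0.45, percentile 9.39, adjusted p = 0.0988, and adjusted p = 0.589 with an estimated correlation), although it did without IgG array 1 (adjusted p = 0.0419) or RBP array 2 (adjusted p = 0.0193), in a range from 0.0193 to 0.866 over 15 alternatives, and its direction turned with quantile normalization. Its median was 0.28 without IgG array 2 and 0.28 without RBP array 1. After centring on the chemosensory genes 14 genes of the list were higher and 0 lower. With the level trend removed 0 were higher and 4 lower. Nr3c1, Igf2bp1, Lmo4 and Gata2 then differed by 0.82, 0.27, 0.05 and 0.04, and none was called. Of 26 glucocorticoid-responsive genes, 8 were higher and 1 was lower (8 and 2 when adjusted over the list alone, 1 and 1 with the level trend removed). The receptor co-chaperones Fkbp5 (1.59 ± 0.19, limma adjusted p = 0.00570) and Fkbp4 (1.06 ± 0.15) and the transcription factor Klf9 (1.48 ± 0.26) were among them, of which Fkbp4 lost its call without RBP array 1 (adjusted p = 0.0599). The number of higher genes was 3 without RBP array 1, 4 without RBP array 2 and 5 with quantile normalization, and 3 were lower without IgG array 2. This list was not called either (median 0.28, percentile 38.5, camera adjusted p = 0.223, and adjusted p = 0.589 with an estimated correlation). Its median was 0.14 without IgG array 2, 0.06 without RBP array 1 and 0.51 without RBP array 2.

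Among marker genes of other fetal liver cells, the number called and the direction depended on the scaling and on single arrays. Of 100 such genes, 3 were higher and 7 lower, but 13 were higher and 1 lower after centring on the chemosensory genes, and 2 were higher and 2 lower with quantile normalization. Without IgG array 1 the counts were 5 higher and 8 lower, without IgG array 2 4 and 12, without RBP array 1 1 and 2, and without RBP array 2 6 and 1. The macrophage genes Cd68 (-1.59 ± 0.18, SE; limma, adjusted p = 0.00568) and Marco (-0.76 ± 0.19) were the 2 of 16 called, with 1 lower when adjusted over the list alone. Of 20 granulocyte and mast cell genes 3 were lower, with 2 when adjusted over the list alone, and these were the neutrophil granule genes Elane (-1.44 ± 0.41, limma adjusted p = 0.0461), Ngp (-0.79 ± 0.16) and Camp (-0.63 ± 0.14). Of 18 endothelial and stromal genes, Tek (1.92 ± 0.16, limma adjusted p = 0.00558) and Pdgfrb (1.09 ± 0.27) were higher and Lyve1 (-0.52 ± 0.14) and Acta2 (-0.52 ± 0.14) lower, with 1 higher when adjusted over the list alone. Marco, Elane, Ngp, Camp, Lyve1 and Acta2 kept their direction but lost their calls after centring on the chemosensory genes. Ngp lay below the background level of 5.34 in both groups and Marco and Lyve1 in the RBP arrays, so the sizes of their differences are uncertain. Of 11 megakaryocyte genes the platelet glycoprotein Gp9 was higher (0.82 ± 0.15, limma adjusted p = 0.0141), and 1 was higher when adjusted over the list alone. Cd68 and Tek kept their calls without each array in turn. Elane was lost without RBP array 2 (limma, adjusted p = 0.161), Pdgfrb without RBP array 1 (0.139), and Marco, Ngp, Camp, Lyve1, Acta2 and Gp9 without RBP array 1 and without RBP array 2 (0.0800 to 0.319), while Marco, Elane, Pdgfrb and Acta2 were also lost without IgG array 1 (0.0556, 0.132, 0.0649 and 0.0579) and Pdgfrb and Lyve1 without IgG array 2 (0.0646 and 0.0504).

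limma called 0 of 19 hepatocyte genes and 0 of 16 lymphoid genes, also when adjusted over the list alone, while 1 and 3 had an unadjusted p under 0.05 and 0 passed without variance moderation. With 1 array left out, limma called 1 hepatocyte gene lower without IgG array 1 and 2 without IgG array 2, and 2 lymphoid genes higher without IgG array 1, 1 lower without IgG array 2 and 1 higher without RBP array 2. After centring on the chemosensory genes 1 of each list was higher. The largest differences among them were 0.46 ± 0.32 for Trf, -0.43 ± 0.24 for Fabp1, -1.28 ± 0.49 for Igll1 and 1.24 ± 0.40 for Rag1, with limma adjusted p from 0.0648 to 0.30, and Fabp1 lay below the background level in both groups. Without IgG array 2 Igll1 (adjusted p = 0.0108) and Fabp1 (0.0174) passed, and Rag1 did without IgG array 1 (0.0406), without RBP array 2 (0.0391), after centring on the chemosensory genes and with either filter on level. The list medians were -0.20 for macrophage, -0.16 for granulocyte and mast, -0.13 for endothelial and stromal, -0.14 for lymphoid, -0.08 for hepatocyte and 0.04 for megakaryocyte genes, and the 5 negative ones turned positive under both scalings but stayed below the median of all genes. Without IgG array 1 the medians of the macrophage, granulocyte and mast, endothelial and stromal, hepatocyte and megakaryocyte lists were -0.12, 0.01, -0.04, 0.03 and 0.24. Without IgG array 2 the 6 medians were, in the order above, -0.31, -0.34, -0.24, -0.29, -0.31 and 0.16. Without RBP array 1 the granulocyte and mast, endothelial and stromal, hepatocyte and megakaryocyte medians were -0.32, -0.23, -0.30 and 0.09, and without RBP array 2 the granulocyte and mast, lymphoid, hepatocyte and megakaryocyte medians were -0.04, -0.21, -0.04 and -0.01. The endothelial and stromal mean was 0.09, opposite in sign to its median. Camera called none of these 6 lists, with adjusted p of 0.0761 for macrophage, 0.0645 for granulocyte and mast, 0.406 for endothelial and stromal, 0.744 for megakaryocyte, 0.223 for hepatocyte and 0.172 for lymphoid genes. Among genes above the median gene it did call the granulocyte and mast list lower (camera, adjusted p = 0.0414). The granulocyte and mast list was called lower after centring on the chemosensory genes (adjusted p = 0.0236), without IgG array 2 (0.0169) and without RBP array 1 (0.00166), in a range from 0.00166 to 0.658 over 15 alternatives. Without RBP array 1 the hepatocyte (0.0368) and macrophage (0.0203) lists were called lower too, in ranges from 0.0368 to 0.825 and from 0.0203 to 0.866, and the direction of the megakaryocyte list turned (0.862), as it did with quantile normalization (0.915). With an estimated correlation, adjusted p was 0.466, 0.610, 0.769, 0.769, 0.728 and 0.582 for the lists in this order.

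Many small RNAs, histone mRNAs and ribosomal protein mRNAs were depleted. Of 363 small RNA genes, 124 were lower and 239 did not pass, with 130 lower when adjusted over the list alone. The nucleolar RNAs Snord82 (-3.56 ± 0.66, SE), Snord118 (-3.31 ± 0.26), Snord47 (-3.25 ± 0.63) and Snord15b (-3.09 ± 0.52) led, with limma adjusted p from 0.00558 to 0.0150. Small RNAs above the chemosensory level had array medians of 7.06 and 7.61 with IgG and of 5.88 and 6.28 with the RBP antibody. Of 30 replication histone genes, 18 were lower and 1 was higher (19 and 1 when adjusted over the list alone). H2bc22 differed by -1.81 ± 0.39 (limma, adjusted p = 0.0203) and H4c3 by -1.80 ± 0.35, beside H2bc3 and H2bc9 above. Of 62 ribosomal protein genes, 17 were lower and 1 was higher, as when adjusted over the list alone. Rpl12 (-1.60 ± 0.42, limma adjusted p = 0.0366), Rpl23a (-1.36 ± 0.29), Rpl26 (-1.26 ± 0.15) and Rps12 (-1.19 ± 0.15) led. Histone genes share sequence with one another, and ribosomal protein genes with pseudogenes, so single genes of both groups are uncertain, as is the size of the difference of H2bc22, whose RBP level of 4.86 lay below background. Without 1 of the RBP arrays H2bc22, H4c3, Rpl12 and Rpl23a lost their calls (limma, adjusted p up to 0.0640, 0.0525, 0.121 and 0.0763), and Rpl12 did after centring on the chemosensory genes. The numbers of lower small RNAs, histones and ribosomal proteins were 37, 9 and 2 without RBP array 1, and 69, 5 and 3 without RBP array 2. After centring they were 73, 12 and 7, with 3 ribosomal protein genes higher. With quantile normalization 74 small RNAs were lower, and without IgG array 2 27 ribosomal protein genes were lower.

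The medians of these 3 lists were -0.53, -0.74 and -0.37, against -0.17, 0.34 and 0.58 for random lists of like level. Camera called each lower (adjusted p = 1.98e-20, 8.80e-09 and 1.49e-07), with adjusted p = 0.178, 0.381 and 0.466 with an estimated correlation. In fry, which tests whether a list moves on balance one way, the small RNAs passed (adjusted p = 0.0224) but the histones (adjusted p = 0.0697) and ribosomal proteins (adjusted p = 0.166) did not. All 3 medians stayed negative with quantile normalization (-0.21, -1.0 and -0.56) and after centring on the chemosensory genes (-0.21, -0.42 and -0.05). Without IgG array 1 the ribosomal protein median was -0.24.

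The chemosensory receptor genes served as a background list, since such receptors are used in sensory neurons. Of 1239, 137 were lower and 1 was higher, and none passed when adjusted over the list alone, where 343 were lower and 1 higher at an unadjusted p under 0.05 in limma and 0 passed without variance moderation. Olfr195 (-1.41 ± 0.29, SE; limma, adjusted p = 0.0187), Olfr603 (-1.21 ± 0.15), Olfr566 (-1.17 ± 0.23) and Olfr1347 (-1.16 ± 0.16) differed most, all but Olfr1347 at RBP levels below the background level of 5.34. Olfr195, Olfr566 and Olfr1347 lost their calls without RBP array 1 (limma, adjusted p = 0.0733, 0.0891 and 0.0549), Olfr195 also without RBP array 2 (0.0596). The number of lower receptor genes was 1 without RBP array 1, 3 without RBP array 2, 235 without IgG array 1 and 340 without IgG array 2, and it was 3 with quantile normalization and 22, beside 8 higher, after centring. Of 1230 predicted gene models, 170 were lower and 55 higher (89 and 39 when adjusted over the list alone), with Gm10785 at -2.61 ± 0.15, 1700054O19Rik at -2.34 ± 0.55 and G530011O06Rik at -2.09 ± 0.33 among the lower and Gm4759 at 2.34 ± 0.23 among the higher. The IgG level of Gm4759 (4.51) lay below background, and 1700054O19Rik lost its call without RBP array 1 (limma, adjusted p = 0.0823). The balance of predicted models turned to 118 higher and 56 lower after centring and to 26 higher and 12 lower without RBP array 1, and was 23 and 26 without RBP array 2, 65 and 303 without IgG array 2, and 29 and 71 with quantile normalization. The medians of -0.29 and -0.26 became 0.03 and 0.03 with quantile normalization and 0.03 and 0.06 after centring on the chemosensory genes, and both stayed below the median of all genes. Camera called both lists lower (adjusted p = 2.21e-16 and 1.05e-09), with an adjusted p of 0.178 for each with an estimated correlation. The chemosensory list was no longer called with the level trend removed (adjusted p = 0.163).

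**Figure D3:**
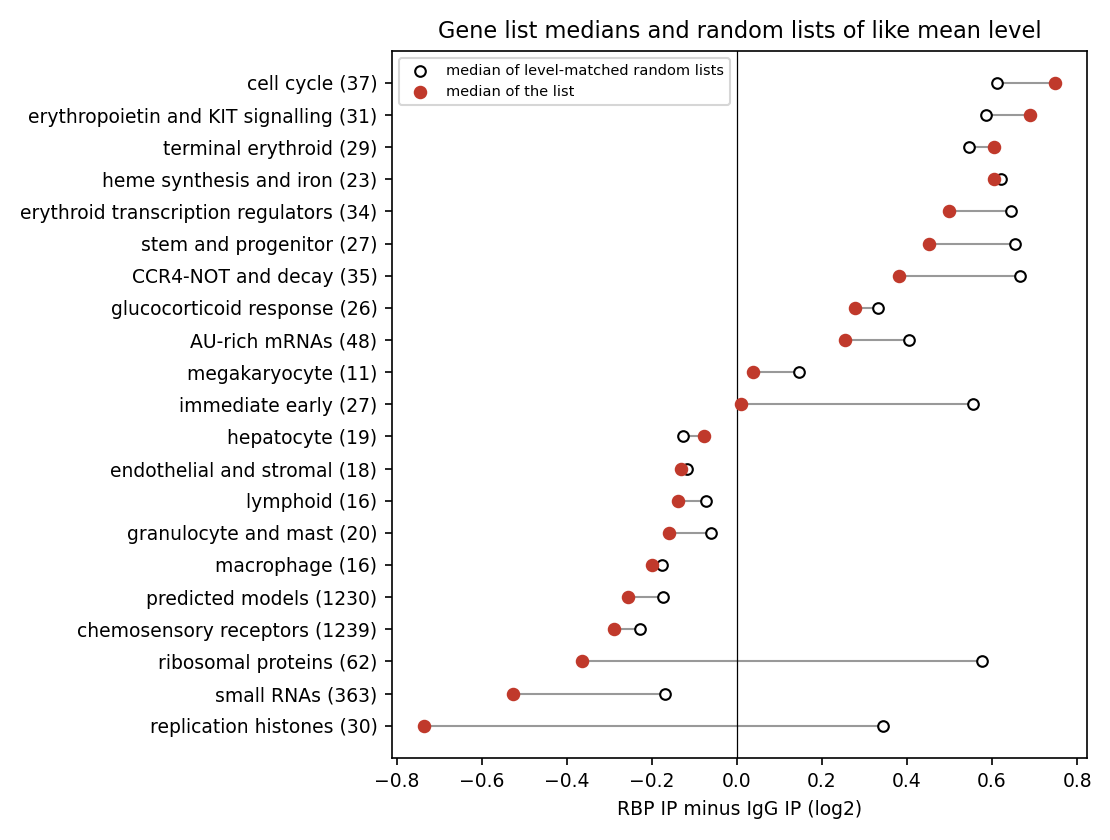
Median difference between the RBP and IgG immunoprecipitates (log2) of the 21 gene lists (filled, with the number of genes measured) and of 10000 random lists of like mean level (open). The cell cycle list lies highest at 0.75, and the ribosomal protein, small RNA and replication histone lists lie lowest, left of their random lists.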

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

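Both results here come from a planned limma fit over all 35556 probe sets, and no test was chosen after its result was seen. They concern probe sets that the comparisons above did not use. Of the 12146 probe sets with no gene name in the annotation, 596 were higher with the RBP antibody than with IgG and 1428 were lower. Of the 1621 probe sets that match several genes, 56 were higher than with IgG and 99 lower. The medians of these probe sets were -0.39 and -0.43. Over all probe sets the same fit gave 4122 higher and 1997 lower, with a median of -0.16.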

How the results depend on the processing

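The level trend removal and the array weights were chosen after the results were seen, and the other settings before. The cause of each change below was not tested, except where fewer genes or arrays entered. Genes higher numbered 4741 and lower 1304, and by the 2-fold rule 2690 and 246. With quantile normalization the 4 counts were 2207, 553, 1335 and 368. Centring on the chemosensory genes gave 317 lower, and 4672 and 118 by the 2-fold rule. Level trend removal gave 999 higher, with 548 and 726 by the 2-fold rule. Above the median gene 564 were lower, over all probe sets 1997, against a 1.2-fold change 365, and at an adjusted p under 0.1 2671. Without variance moderation limma called 2 higher and 1 lower. Without each array in turn, genes higher ran from 1724 to 5153, lower from 99 to 2905, 2-fold lower from 266 to 446 and lists lower from 5 to 9. A group left with 1 array was assumed to vary like the other. Without an RBP array the IgG pair, which spread more, thus set the variance, and a lost call need not mean a smaller difference. No gene called in any setting had the opposite call in the reported fit.

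The replicate number as a block gave 5885 higher and 2199 lower and, among lists, made the granulocyte and mast list lower as well (adjusted p = 0.0389). Of the 100 marker genes of other cells it called 14 higher and 12 lower, against 3 and 7, among them 3 lymphoid genes higher and 2 lower. The numbers are not stated to mark a shared preparation. The deviations of same-numbered arrays correlated at 0.255 across genes and at 0.685 across small RNAs, positive as a shared preparation would give, but with 2 pairs this leaves the pairing undecided. The r between the differences of same-numbered arrays was 0.817, and 0.706 with quantile normalization, 0.730 with the trend removed, and 0.80, 0.820 and 0.818 above the median gene, above the chemosensory level and with probe-set means.

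Lists called higher fell from 6 to 1 (cell cycle) with quantile normalization, 1 (cell cycle) above the chemosensory level, 0 above the median gene, 0 with the trend removed and 0 with an estimated correlation. Lists called lower numbered 5, and 3 with fry, which did not pass ribosomal proteins and histones, and 0 with an estimated correlation. Directions turned for lists that were not called after the turn. With quantile normalization these were stem and progenitor, AU-rich, CCR4-NOT and megakaryocyte (adjusted p = 0.568, 0.913, 0.759 and 0.915), and the same lists above the median gene (0.427, 0.678, 0.678 and 0.737). With the trend removed they were heme (0.878), erythroid regulators (0.547), stem (0.334), AU-rich (0.752), glucocorticoid (0.921), CCR4-NOT (0.50), megakaryocyte (0.866) and endothelial (0.921). Immediate early and endothelial lists turned with fry (0.825 and 0.940). Without single arrays, immediate early ran from 0.0442 to 0.996, turned without IgG array 1 or RBP array 2, and megakaryocyte from 0.633 to 0.862, turned without RBP array 1. Genes that turned were Gata1 (-0.20), Hbb-bh1 (0.0015) and Actb (0.16) with quantile normalization, Actb (0.15) with centring, and Gata1 (-0.48), Klf1 (-0.23) and Myb (-0.21) with the trend removed.

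Of the 105 named genes, 25 lost their call with quantile normalization, 9 with centring, 42 with the trend removed, 30 and 28 without RBP array 1 or 2, and 95 without moderation. A test of AU-rich motifs in untranslated regions, planned for the case that transcripts were given, was not run. Signal near background limits the 7030 dimmest genes.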

Other observations

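The gene families in this part, the removal of the level trend, and the tests of the authors' scaling, of a single IgG array and of level as the source of the low small RNAs and ribosomal proteins were chosen after the results were seen. The tests of the spread beyond the level trend, of the AU-rich and terminal erythroid lists and of the respiratory chain were written down before their own results. The bootstrap intervals in this part are over genes, which are not independent replicates, so they do not measure the spread between arrays.

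Many motor protein, deubiquitinase and zinc finger genes were enriched with the RBP antibody, in families picked after the results had been seen. Of 38 kinesin genes 22 were higher, led by Kif3a, a motor of cilia and vesicle transport (2.03 ± 0.15, SE; limma, adjusted p = 0.00558), Kif13a (1.82 ± 0.19) and Kif3b (1.61 ± 0.15). The IgG level of Kif3a (5.19) lay below the background level of 5.34, so the size and rank of its difference are uncertain. Of 55 ubiquitin-specific proteases 35 were higher and 3 lower, with Usp47 at 1.91 ± 0.15 and Usp30 at 1.73 ± 0.20. Of 347 zinc finger genes with a Zfp symbol, 124 were higher and 7 lower, with Zfp146 at 2.01 ± 0.19 and Zfp507 at 1.90 ± 0.15. The family medians of 0.80, 0.89 and 0.53 compare with 0.24, 0.38 and 0.05 for random lists of like level. The numbers of higher genes fell to 11, 18 and 62 without RBP array 1 and to 13, 17 and 52 without RBP array 2. The family medians stayed positive with quantile normalization (0.45, 0.56 and 0.55) and with the level trend removed (0.26, 0.31 and 0.31). Higher genes numbered 15, 20 and 94 with quantile normalization (0, 1 and 8 lower) and 9, 7 and 56 with the trend removed (0, 2 and 15 lower). After centring on the chemosensory genes 24, 38 and 213 were higher. Camera gave adjusted p of 8.95e-05, 1.54e-05 and 1.54e-06, and an adjusted p of 0.179 for each with an estimated correlation. As the families were picked on the same arrays, these values are no independent evidence of enrichment.

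Among mitochondrial genes, the mitochondrially encoded ND3 and COX2, the 2 measured, were lower by limma, COX2 at -1.56 ± 0.18 (adjusted p = 0.00568). Of 85 nuclear genes of the respiratory chain and its assembly, 10 were higher and 3 lower, with a median of -0.02 that was 0.17 without IgG array 1, -0.28 without IgG array 2, 0.30 after centring on the chemosensory genes and -0.24 with quantile normalization. The counts were 23 higher and 3 lower without IgG array 1, 8 and 24 without IgG array 2, 27 higher after centring, and 4 and 11 with quantile normalization. Without RBP array 1 and without RBP array 2, 5 and 2 were higher. Of 77 mitochondrial ribosomal protein genes 11 were higher and 1 lower, with a median of 0.23 that turned to -0.09 with quantile normalization (2 higher, 7 lower). It was 0.49 without IgG array 1 (27 higher), 0.01 without IgG array 2 (11 higher, 8 lower) and 0.54 after centring (26 higher), and 2 were higher without RBP array 1 or without RBP array 2. Camera called neither family (adjusted p = 0.488 and 0.188, and adjusted p = 0.899 for both with an estimated correlation), but both lower with the trend removed (adjusted p = 2.61e-08 and 1.77e-06). Random lists of like level had medians of 0.60 and 0.67. The proteasome genes (12 of 40 higher, 2 lower, median 0.47) lay at percentile 5.34, and camera called them higher (adjusted p = 0.00689) but lower with the trend removed (adjusted p = 0.00645), with adjusted p = 0.401 with an estimated correlation. The higher proteasome genes numbered 2 without RBP array 1, without RBP array 2 and with quantile normalization, and 27 after centring.

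Abundant genes lay higher with the RBP antibody, which a shift set by level alone could give. With the level trend removed, the spread of differences among 12908 genes above the chemosensory level was 2.43 times (bootstrap 95% interval 2.36 to 2.5) that predicted by replicate arrays, but these replicates may be technical, so the ratio decides nothing and this shift stays open. The authors' scaling stays open too: quantile normalization, which gives all arrays 1 distribution, cut the gap between genes above and below that level from 0.62 to 0.10 and the higher genes from 4741 to 2207. Centring on the chemosensory genes (7081 higher) adds a constant to each array and does not bear on the trend. The narrower range of the IgG arrays goes with the antibody in this design, so a compressed IgG signal and broad mRNA recovery by the RBP antibody cannot be told apart here.

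The depletion of small RNAs may reflect what control IgG and beads retain, a hypothesis not tested here. IgG array 2 had the highest small RNA values, but without it the median of 143 small RNAs above the chemosensory level was -0.97 (bootstrap 95% interval -1.11 to -0.82), against -1.14 with all arrays. For these 143 the level trend runs the other way, so its removal had to lower the median, to -1.47 (-1.76 to -1.14). Over all 363 small RNAs its removal moved the median from -0.53 to -0.32 and the lower genes from 124 to 86. The trend may thus give part of the difference of the dimmer ones. The values argue against IgG array 2 as the whole cause and, for the 143 alone, against the level trend. The kit's recovery of short RNAs was not measured.

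Histones, ribosomal proteins and small RNAs are all short, so a candidate explanation is that short RNAs lie lower in the RBP IP whatever they encode, IP standing for immunoprecipitate. Level alone is argued against for the ribosomal proteins, whose median was -0.37 against 0.58 for random lists of like level. As the median of those random lists was positive, removing the level trend had to lower the median of the ribosomal proteins further. It was then -0.93 (bootstrap 95% interval -1.03 to -0.85), which adds no separate evidence. The length hypothesis predicted that nuclear-encoded respiratory chain subunits, taken to be another group of short mRNAs, would lie low among genes of their level. The genes ranked were the 85 of the respiratory chain and its assembly, so assembly factors were included. Their median fell at percentile 0 of 10000 random lists, as it did without each array in turn and under both other scalings. This leaves RNA length open beside the antibody's choice of RNA, since lengths were not used here and a shared feature of these mRNAs other than length would give the same result.

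If the protein is ZFP36L2, which the labels do not say, a hypothesis is that AU-rich mRNAs would be enriched beyond others of like level. Their median lay at percentile 15.79, and at 3.67 to 75.43 without each array in turn, below the bound set beforehand. The same hypothesis for terminal erythroid mRNAs gave percentile 65.09, and 44.7 to 81.6 without each array in turn. On these arrays the medians of these 48 and 29 genes did not stand out from other genes of like level. The levels matched on include the RBP arrays, and the percentiles are not tests. An enrichment of either list beyond other genes stays undecided, and the values do not argue against enrichment over IgG. They say nothing about single members such as Cxcl2, or about AU-rich mRNAs outside the list.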
